A study of Mus musculus with 12 samples.

How the data were processed

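Skin RNA of 12 mice (4 littermate, 4 CLE, 4 Merkel het CLE) was measured on a NanoString mouse immunology panel. RNA was extracted with a Qiagen column kit and probes were labelled after the manufacturer's protocol, per the labels' protocols. The deposited table holds 561 gene probes and 14 control probes (6 positive, 8 negative). The deposited signal of each gene probe is a count of hybridised barcodes multiplied by 1 factor per lane, as the steps between the values show; which factor the authors used is not given in the sources used here. The deposited control values are raw counts. Since all gene values of a lane above a floor of 1 are multiples of 1 step, whole counts were recovered in the 12 lanes. Of these values, 100% lay within 0.02 units of a multiple of the step. In Merkel het CLE 1 and 3, 3 and 2 values lie at the floor of 1, and these were taken as whole without this check. The lane factors ran from 0.716 to 5.56. Values are given in units of the deposited signal.

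Groups, replicate numbers, disease scores and genotypes follow the labels; replicate numbers are in the order of the sample accessions. The series description and the sample labels differ: the description gives all groups as lacking TLR9 and the Merkel het CLE mice as having lost Merkel cells. The sample labels give 2 wt/wt mice and 1 ko/wt mouse and a partial loss. The sample labels were followed, and which is right was not tested. Of the gene probes, 549 matched a mouse gene symbol in the reference table, from which only names were taken, and 12 did not. A gene was tested if its recovered count exceeded the mean plus 2 SD of the lane's negative controls in at least 4 of the 12 libraries. This left 451 genes; 98 lay below background and the 12 reference genes were not tested. Recovered gene counts ran from 99297 to 682046 per library. The fold scale is log2(value + 1), which understates differences of genes with low values. For some genes a lower bound of the estimated difference is given. These were below background in all libraries of a group and above it in all of the other. The bound takes the background thresholds of the low libraries in place of their values. It covers background but not the spread between mice.

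Differences between groups were tested with limma (version 3.58.1, R 4.3.3) on log2(value + 1), with all 12 libraries in 1 fit of group means and a variance trend. Adjusted p-values are Benjamini-Hochberg values over the 451 genes, with a threshold of 0.05; the ± values of log2 differences are moderated standard errors. A trend with the skin disease score was fitted in the 8 diseased mice with group as a term. Tests between groups with edgeR (version 4.0.16) used the recovered counts. Gene lists were fixed in advance, and the 25 with at least 3 tested members were tested with fry of limma, adjusted over the 25 lists; camera with an estimated correlation or a preset correlation of 0.01, and an exact permutation test of the list means, were run beside it. Members of each list were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

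Groups, tests, thresholds, lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. Genes are named by this rule: Tlr9; of the genes past the threshold without overlap between the groups, the 10 largest rises and the 10 largest falls; for each list described, up to 4 members past the threshold with the largest absolute change, or, where none passed, those with the smallest unadjusted p; and where fewer than 10 genes passed, the 10 with the smallest unadjusted p. A few genes that the rule names are not reported here. Which lists are described in which comparison was chosen after the results were seen. The 25 lists cover type I interferon, interferon-gamma, MHC class I and II, T cells, cytotoxic and NK cells, Th1, Th2, Th17, regulatory T cells, B cells, macrophages, neutrophils, dendritic cells, mast cells, complement, chemokine ligands and receptors, IL-1 family, Toll-like receptors, NF-kB and TNF, co-inhibition, cell death, adhesion and epithelial genes. A list of Merkel cell genes had 1 tested member, and the list of reference genes was not tested.

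Alternatives covered rescaling on the reference genes, median centring, quantile normalization, a filter of at least 50 units in a whole group or none, a pseudocount of 16, no variance trend, robust moderation, array weights, edgeR, fits of 2 groups, TLR9 genotype (ko/ko libraries alone, or as a covariate), leaving out K14Cre+ littermates, the title number (as a random block, or the number 23 alone), the disease score as a covariate, other thresholds, and leaving out each library. After the data were seen, background subtraction, a filter for genes above background in all 12 libraries, leaving out littermate 2 and CLE 1, and leaving out each library in the list tests were added.

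The code was tested on simulated data with each lane's depth and background, in 20 draws with 200 of 451 genes changed. For CLE against littermates, limma recovered 25.8%, 70.4% and 85.1% of genes changed 2-, 4- and 8-fold. For Merkel het CLE against littermates the shares were 32.9%, 82.0% and 93.8%, and for Merkel het CLE against CLE 35.3%, 80.2% and 93.6%. Of the calls, 2.15%, 2.56% and 3.44% were unchanged genes. Changing so many genes eases the adjusted threshold. Genes were drawn independently, with the same spread in all groups. In the data the spread differed, as the SD of the neutrophil list mean was 2.35 in CLE and 0.634 in littermates. The shares therefore do not give the power of comparisons with few calls. The simulated overlap of the 2 contrasts used 100 draws of unchanged groups.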

Results

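RNA from the skin of 12 female mice was measured with a NanoString mouse immunology panel, in which barcoded probes are hybridised to each transcript and counted one by one. All mice had received OT2 cells, which are CD4 T cells with a transgenic receptor for an ovalbumin peptide. The cells had been grown for 10 days under conditions that favour the T helper 2 (Th2) state. Skin was taken when disease first appeared, about 3 to 4 weeks after transfer. The 4 mice of the CLE group (a model of cutaneous lupus erythematosus) belonged to the parental strain, expressed the autoantigen in the skin and kept their Merkel cells, the touch-sensing cells of the epidermis. The 4 mice of the Merkel het CLE group also expressed the autoantigen and carried 1 floxed copy of Atoh1 with K14Cre. Atoh1 is a transcription factor needed for Merkel cells to form, and K14Cre acts in the epidermis, so the labels describe a partial loss of these cells. The 4 littermates received the same T cells but could not express the autoantigen; littermates 3 and 4 carried K14Cre and are described as having lost part or all of their Merkel cells. Each library came from a different mouse, so p-values measure the spread between mice. Some mice share a title number, whose meaning is not given in the sources used here, so they may not be independent. Taken as a random block, the title number had a consensus correlation over genes of 0.213.

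Skin disease scores were 2.5, 1, 1 and 3 in CLE mice 1 to 4 and 3, 2, 2 and 2.5 in Merkel het CLE mice 1 to 4, and 0 in the littermates. The counts behind the values differed widely between libraries. Merkel het CLE 1 had 682046 recovered gene counts, while littermate 2 had 99297 and CLE 1 had 134994. The deposited values of these low-count libraries had been multiplied by 4.04 and 5.56, so their negative controls stood at 50.04 and 62.5 units. In the other 10 libraries the negative controls stood between 9.66 and 27.5 units. Of the gene probes, 295 passed the background threshold in littermate 2 and 473 in CLE 4. Values near background were therefore read with less precision in littermate 2 and CLE 1 than elsewhere.

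**Figure D1:**
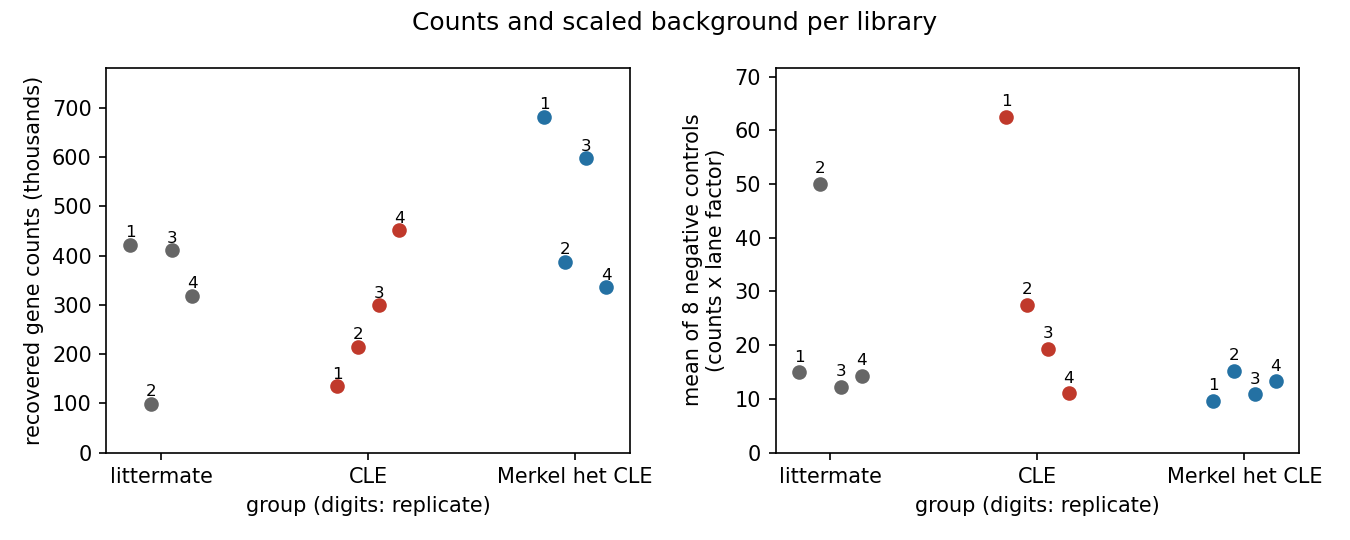
Recovered gene counts (left) and the mean of the 8 negative controls after scaling (right) for each library, with digits giving the replicate within a group. Littermate 2 (99297 counts) and CLE 1 (134994 counts) had the fewest counts and the highest scaled background, at 50.04 and 62.5 units.

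Tlr9, the endosomal receptor for unmethylated CpG DNA, is the gene that most of these mice are labelled as lacking. The 9 libraries labelled TLR9 ko/ko had a median Tlr9 value of 40.5 units, against 39.2 in the other 3. Among Merkel het CLE mice, the wild-type libraries 1 and 2 read 55.8 and 39.2 units, and the ko/ko libraries 3 and 4 read 46.4 and 27.4 units. The ko/wt littermate 1 read 21.7 units, and the ko/ko littermates 2 to 4 read 109, 36.5 and 31.5 units. The CLE libraries, all ko/ko, read 156, 34.6, 40.5 and 42.9 units. The highest of these values came from CLE 1 and littermate 2, the libraries with the highest scaled background. The sources used here do not say whether the probe lies in the deleted part of the gene, so Tlr9 does not check the genotype labels. The log2 difference was 0.43 ± 0.56 (SE, n = 4 per group) for CLE against littermates, 0.0036 ± 0.56 for Merkel het CLE against littermates and -0.43 ± 0.56 for Merkel het CLE against CLE. The limma adjusted p was 0.612, 0.996 and 0.712.

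The first comparison asked what autoantigen-bearing skin with its Merkel cells expressed relative to littermate skin. No single gene passed, so the following are values without a call. The interferon-induced chemokines Cxcl10 and Cxcl9, which attract T cells through Cxcr3, had log2 differences of 4.02 ± 0.87 and 3.98 ± 1.05 (SE, n = 4 per group). Cxcl10, Cxcl9 and S100a9 were above background in 3 of 4 littermates and in all CLE libraries. Cxcl10 averaged 2243 ± 1542 units in CLE and 85.2 ± 28.6 in littermates (SD, n = 4). The calcium-binding alarmins S100a9 and S100a8, abundant in neutrophils and inflamed keratinocytes, had differences of 5.26 ± 1.47 and 4.98 ± 1.37. The growth-factor gene Tgfb2 (above background in 2 of 4 CLE libraries), its signalling mediator Smad3 and the lipid-presenting molecule Cd1d1 had differences of -1.48 ± 0.38, -0.93 ± 0.23 and -2.17 ± 0.56.

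All 11 tested interferon-gamma-induced genes had positive differences between CLE and littermates, with a median of 1.18, or 0.82 above the median of all genes. None passed over all genes, and 5 were higher when adjusted over the list alone. Besides Cxcl10 and Cxcl9 these included Cd274, the inhibitory ligand PD-L1, at 1.25 ± 0.45. The type I interferon-induced list had 10 of 10 positive differences with a median of 1.03, among them Stat2 at 1.66 ± 0.66, Irf7 at 1.53 ± 0.64 and Ifi35 at 0.99 ± 0.42. None of its members passed, over all genes or adjusted over the list alone. Of 24 chemokine ligands, 23 had positive differences with a median of 1.27, and 6 were higher when adjusted over the list alone. The monocyte attractants Ccl7 and Ccl12 stood at 2.33 ± 0.74 and 1.72 ± 0.58.

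The neutrophil list had a median difference of 2.12 between CLE and littermates, with 6 of 7 members positive and 3 higher when adjusted over the list alone. Its members Cxcr2, the receptor for neutrophil-attracting chemokines, and Csf3r, the receptor for granulocyte colony-stimulating factor, had differences of 3.40 ± 1.14 and 1.96 ± 0.84. Cxcr2 was below background in all 4 littermates and in CLE 3. The mean log2 value of the neutrophil list was 11.9, 8.90, 6.93 and 6.96 in CLE 1 to 4, against 5.17 to 6.69 in littermates. CLE 1 and 2 thus carried most of the difference. Over 29 alternatives the S100a9 difference ran from 3.52 to 8.27. All 16 macrophage and monocyte genes were positive with a median of 1.35, and 0 passed when adjusted over the list alone. Among them were the Fc receptor Fcgr4 at 2.78 ± 0.79, the receptor Lilrb4a at 2.05 ± 0.77, the signalling adaptor Tyrobp at 1.78 ± 0.68 and the scavenger receptor Msr1 at 1.60 ± 0.64. T cell markers were mixed, with 10 of 14 positive, a median of 0.58 (0.23 relative to all genes, 0.11 with median centring and 0.06 with quantile normalization) and 0 past the threshold when adjusted over the list alone. Cd4, Il7r and Icos stood at 0.88 ± 0.43, 0.78 ± 0.42 and 0.76 ± 0.41, and Cd7 at -1.06 ± 0.39. With median centring the medians were 0.70 (interferon-gamma), 0.56 (type I interferon), 0.79 (chemokine ligands) and 0.88 (macrophage). After background subtraction the neutrophil median was 3.85, and the 7 macrophage genes above background in all libraries had 0.62. Msr1 was above background in 1 littermate, Fcgr4, Csf3r and Ccl12 in 2, and Lilrb4a and Ccl7 in 3. In CLE, Msr1, Csf3r, Cd4 and Cd7 were above it in 3 libraries and Icos in 2.

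Other leading genes were Pdcd1lg2, the inhibitory ligand PD-L2, at 1.98 ± 0.45, and the glucocorticoid-responsive Fkbp5 at 1.08 ± 0.28. The transcription factor Nfil3 and the DNA-sensing adaptor Sting1 stood at 1.17 ± 0.31 and 1.82 ± 0.50. Pdcd1lg2 was below background in all 4 littermates and in CLE 1. The transcript NM_019494.1, with no symbol in the reference used, stood at 3.10 ± 0.78 and was above background in 1 littermate and 3 CLE libraries.

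By limma, 0 of 451 tested genes differed between CLE and littermates, with a smallest adjusted p of 0.111. At an unadjusted p under 0.05 there were 120 genes, 91 higher and 29 lower, and edgeR on the recovered counts called 25, of which 24 were higher. The 2 groups did not overlap in 50 genes, or 11.1%, against a chance share of 2.86%. Quantile normalization gave 9 genes (3 higher, 6 lower), array weights 108 (85 higher, 23 lower) and centring on the sample medians 2. The median of all genes lay 0.35 above 0, a shift that centring removes. None of the 25 gene lists passed by fry, with adjusted p from 0.16 to 0.894; the smallest unadjusted p, 0.0079, was that of the chemokine ligands. CLE 3, with a score of 1, lay near the littermates. Without it 138 genes (107 higher, 31 lower) and 11 lists, each higher, passed, including 29 of the 30 genes named for this comparison.

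The second comparison set Merkel het CLE skin against littermate skin. S100a9 and S100a8 rose by 7.11 ± 1.47 and 6.62 ± 1.37 on the log2 scale (SE, n = 4 per group; adjusted p = 0.0246 for both). Expressed as fold changes these were 138 and 98.7. Il1b, the cytokine released after inflammasome activation, rose by 4.62 ± 1.17, and Ptgs2, the inducible enzyme of prostaglandin synthesis, by 4.10 ± 0.95. Of the littermates, 3 had S100a9 and Ptgs2 and 1 had Il1b above background. In the opposite direction, Il12rb2, the signal-transducing chain of the interleukin-12 receptor, fell by 5.02 ± 0.71 (adjusted p = 0.00443), from 600 ± 94.6 units in littermates to 20.3 ± 14.8 units (SD, n = 4), above background in 1 of 4 Merkel het CLE libraries. The transcription factors Irf4 and Gata3 fell by 2.04 ± 0.30 and 1.73 ± 0.38. The T cell receptor chain Cd3e fell by 1.95 ± 0.34 (adjusted p = 0.0114).

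**Figure D2:**
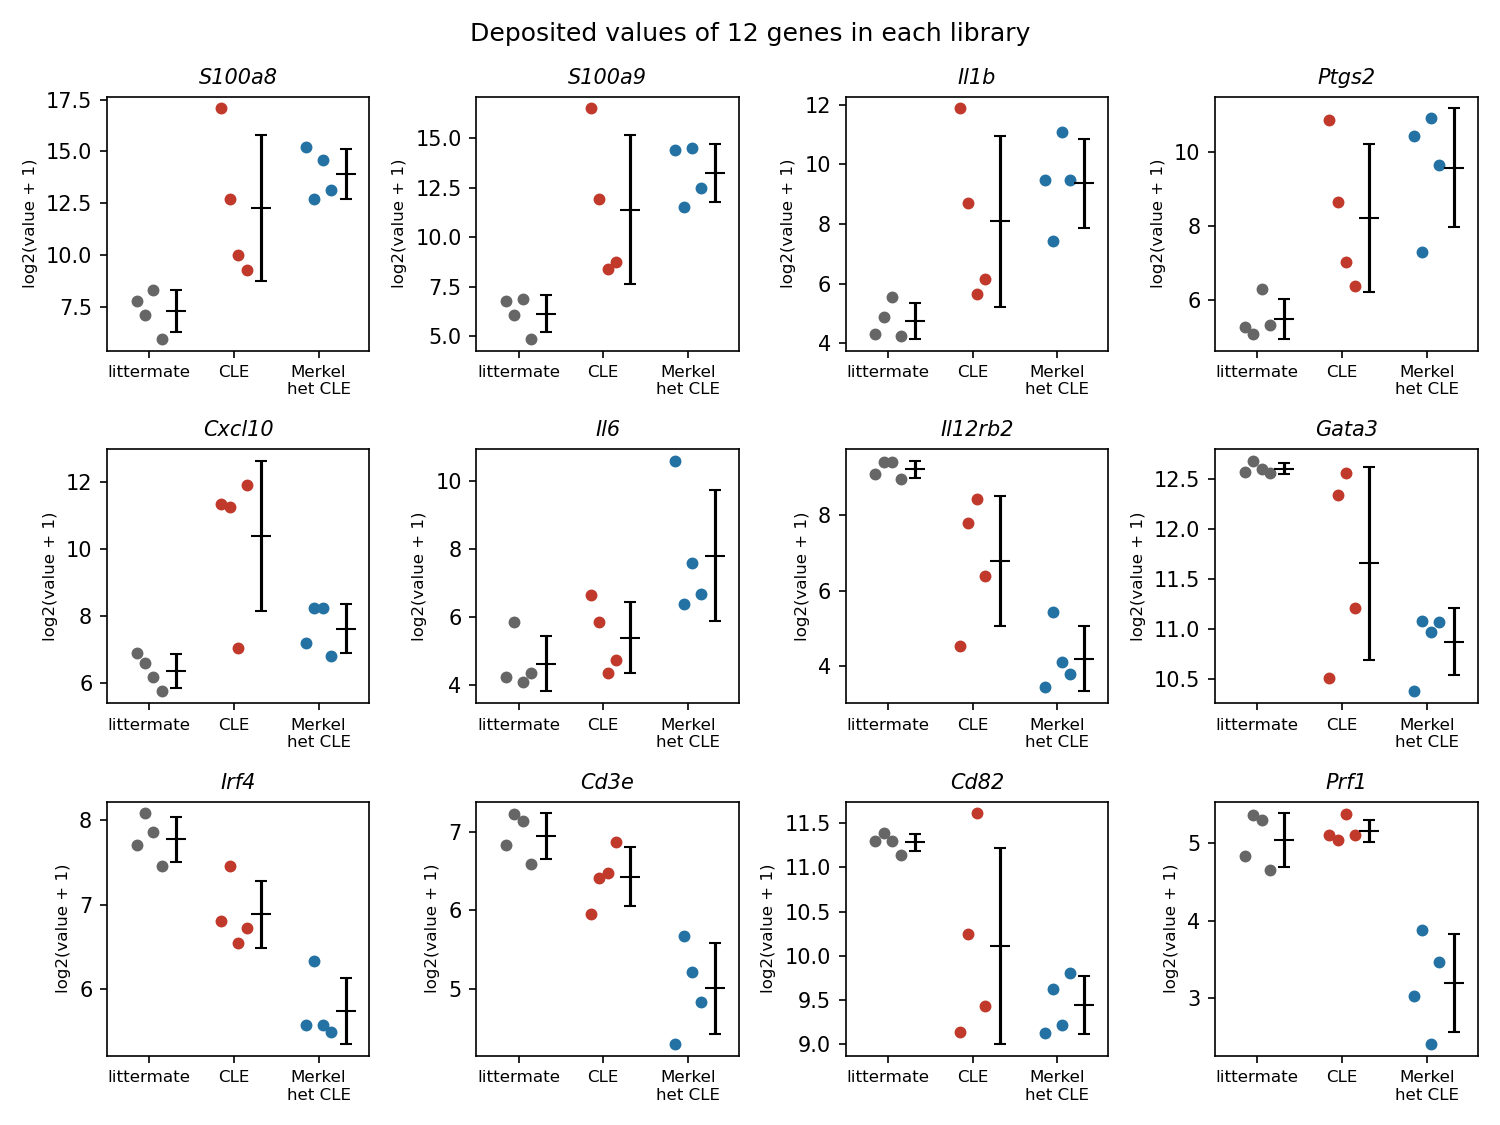
Deposited values of 12 genes as log2(value + 1) in each of the 12 libraries, with bars giving the mean and SD of each group of 4. S100a8, S100a9, Il1b, Ptgs2 and Il6 were higher and Il12rb2, Gata3, Irf4, Cd3e, Cd82 and Prf1 lower in Merkel het CLE than in littermates with no overlap, while Cxcl10 did not pass in any comparison.

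Of the 7 neutrophil genes, 5 rose in Merkel het CLE skin relative to littermates and 2 did not pass; adjusted over the list alone, 5 were higher too. The risers besides S100a8 and S100a9 included Cxcr2 at 4.10 ± 1.14 and the neutrophil attractant Cxcl1 at 3.34 ± 0.95. The list median was 3.34, but the list did not pass by fry (unadjusted p 0.0187, adjusted p 0.31), which adjusts over 25 lists. Among 24 chemokine ligands, 3 rose (Cxcl1, Ccl7 by 2.55 ± 0.74 and Ccl12 by 2.07 ± 0.58) and 1 fell (Xcl1, made by activated T and NK cells, by 1.49 ± 0.43), with the same numbers adjusted over the list alone; the other 20 did not pass and the list median was 1.11. In the macrophage and monocyte list, all 16 members had positive differences (median 1.36), but only Lilrb4a passed, with a rise of 2.90 ± 0.77, and the count adjusted over the list alone was also 1. In the NF-kB and TNF list, Tnfaip6, an anti-inflammatory hyaluronan-binding protein, rose by 2.79 ± 0.66 and the nuclear cofactor Bcl3 by 2.00 ± 0.54. The signalling adaptor Traf2 fell by 0.89 ± 0.26. The other 19 members of that list did not pass, its median was -0.08, and adjusted over the list alone 2 were higher and 2 lower.

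Among T cell markers, 4 of 14 fell in Merkel het CLE relative to littermates, none rose and 10 did not pass, with the same 4 lower when adjusted over the list alone and a list median of -0.49 (-0.83 with median centring, -0.33 after background subtraction and 0.45 in the 2 markers above background in all libraries). They were Cd3e and the other receptor-complex chains Cd247 (fell by 1.43 ± 0.32) and Cd3d (fell by 1.25 ± 0.37), and Cd7 (fell by 1.40 ± 0.39). In the cytotoxic and NK cell list, Xcl1 and Prf1, the pore-forming protein perforin, fell and 9 of 11 members did not pass; adjusted over the list alone 2 were lower, and the median was -0.51 (-0.85 with median centring and -0.35 after background subtraction). Prf1 had a log2 difference of -1.85 ± 0.33 and was below background in all 4 Merkel het CLE libraries and in littermate 2. Of 8 Th1-associated genes, 3 fell and 5 did not pass; adjusted over the list alone 3 were lower and 1 higher. Beside Il12rb2 these were Il18r1, a chain of the interleukin-18 receptor, which fell by 1.73 ± 0.43, and Il12a, a subunit of interleukin-12. Il12a had a log2 difference of -1.54 ± 0.41, with 3 littermates and 0 Merkel het CLE libraries above background. The Th1 list median was 0.10 while its mean was -0.57, so median and mean differed in sign; the median turned to -0.23 with median centring.

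The interferon-gamma-induced genes did not pass in Merkel het CLE against littermates: 0 of 11 over all genes and 0 adjusted over the list alone, with a median of 0.20 that turned to -0.13 with median centring and -0.10 with quantile normalization. Cxcl10 and Cxcl9 stood at 1.26 ± 0.87 and 1.50 ± 1.05, the Fc receptor Fcgr1 at 2.09 ± 0.72 and the nitric oxide synthase Nos2 at -0.73 ± 0.67. Other large rises were those of the fungal-sensing lectin Clec4e and the cytokines Il19 and Il6, at 4.00 ± 1.14, 3.28 ± 0.97 and 3.18 ± 0.85. Clec4e, Cxcr2, Il19 and Il6 were below background in all 4 littermates. With the littermates' background thresholds in place of their values, the estimated rises were 6.43-fold, 8.68-fold, 4.94-fold and 6.63-fold. These are lower bounds of the estimates for background alone. They do not cover the spread between mice, so the rises could be smaller. The chemokine-scavenging receptor Ackr4, the transcription factor Ikzf2 and the tetraspanin Cd82 fell by 2.19 ± 0.51, 1.99 ± 0.46 and 1.84 ± 0.43.

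By limma, 53 of 451 genes differed between Merkel het CLE and littermates, 22 higher and 31 lower, and edgeR called 68 (36 higher, 32 lower). The 2 groups did not overlap in 51 of the 53, and in 138 genes in all, or 30.6%, against a chance share of 2.86%. Subtracting the background gave 59 genes with the split turned to 36 higher and 23 lower. None of the 25 lists passed by fry, with adjusted p from 0.31 to 0.99.

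The count of 53 genes between Merkel het CLE and littermates varied with the libraries in the fit. Leaving out 1 Merkel het CLE library left 7, 59, 9 and 15 genes (libraries 1 to 4 in turn), leaving out 1 littermate left 5, 4, 2 and 5, and leaving out 1 CLE library, which only informs the shared spread, left 81, 30, 94 and 68. With TLR9 ko/ko libraries alone (2 against 3) 0 genes passed by limma (77 at an unadjusted p under 0.05), and without the 2 littermates labelled K14Cre+ (4 against 2) 0 passed (85 unadjusted). All 53 genes kept their sign in each of these fits. For the 51 whose groups did not overlap this was fixed in advance. Leaving out a CLE library cannot change these differences at all. Among libraries whose titles share the number 23 (2 against 2) 10 genes passed, and with the title number as a random block 58.

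The third comparison asked what differed between the disease groups with and without the Merkel cell genotype, and is also the test of whether the first 2 contrasts differ. Prf1 was the 1 gene that passed: it averaged 34.9 ± 3.80 units in CLE and 8.81 ± 4.03 in Merkel het CLE (SD, n = 4), a log2 difference of -1.97 ± 0.33 (limma adjusted p = 0.0261; 95% interval -2.68 to -1.26). It was above background in 2 CLE libraries and in 0 Merkel het CLE libraries. CLE 1 and CLE 2 had 6 and 13 recovered Prf1 counts, below their thresholds of 19.1 and 21.6, so their values cannot be told from scaled background and no lower bound of the difference can be given. Of the 25 lists, 6 were lower in Merkel het CLE as groups: regulatory T cell, cytotoxic and NK cell, co-inhibitory, T cell, Th1-associated and cell death genes. By fry their adjusted p was 0.0156, 0.0178, 0.0178, 0.0218, 0.0411 and 0.0166. None of the 6 passed by camera with an estimated correlation, where adjusted p was 0.563 for the first 3 and 0.625 for the other 3. Camera sets a list against the other genes of this immunology panel, while fry tests the list's own genes across libraries. The questions differ, so the loss cannot be put down to correlation alone. Over all alternatives the lowest adjusted p of these 6 lists was 0.00288, 1.33e-04, 0.00288, 0.00444, 0.00815 and 0.00444. The highest values were those of camera with an estimated correlation, while the 1.33e-04 of the cytotoxic list came from camera with the preset correlation. With a preset correlation of 0.01, camera, which sets a list against the other genes of the panel, called 9 lists. The cytotoxic, co-inhibitory, T cell, regulatory T cell and MHC class I lists were lower, and the epithelial, neutrophil, adhesion and macrophage lists higher (adjusted p = 0.0136, 0.0317, 0.0345 and 0.0366 with the preset correlation). With an estimated correlation these 4 had adjusted p = 0.581, 0.705, 0.705 and 0.875, and MHC class I 0.625. Th1-associated and cell death genes did not pass there (0.176 and 0.161).

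All 11 cytotoxic and NK cell genes had negative differences between Merkel het CLE and CLE, with a median of -1.27. Only Prf1 passed, and 7 were lower when adjusted over the list alone. Without passing over all genes, the granzyme gene Gzma stood at -2.64 ± 0.57 and Xcl1 at -1.89 ± 0.43 (adjusted p = 0.063 for both). Among T cell markers 0 of 14 passed and 7 were lower adjusted over the list alone, with a median of -0.74 and 11 negative. The T cell receptor kinase Zap70 stood at -1.66 ± 0.39, Cd3e at -1.43 ± 0.34, Cd3d at -1.45 ± 0.37 and the costimulatory receptor Cd27 at -1.41 ± 0.42. The 5 regulatory T cell genes were all negative with a median of -1.02; 0 passed and 2 were lower adjusted over the list alone. They were led by Il2rb, a chain of the interleukin-2 receptor, at -1.36 ± 0.35, Ikzf2 at -1.11 ± 0.46, the checkpoint receptor Ctla4 at -1.02 ± 0.38 and Il2ra at -0.75 ± 0.47. Il2ra stood at 0.0813 after background subtraction. Cd27 was above background in 1 Merkel het CLE and 3 CLE libraries, Ctla4 in 2 and 3, Il2ra in 3 and 2 and Cd3e in 3 and 3, and Gzma and Cd3d in 3 and 4, so the sizes of these differences are uncertain.

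The 7 co-inhibitory genes were all negative in Merkel het CLE relative to CLE (median -1.02); 0 passed and 5 were lower adjusted over the list alone. Pdcd1lg2 (above background in 2 Merkel het CLE and 3 CLE libraries) stood at -2.01 ± 0.45, the receptor Cd244a at -1.29 ± 0.45 and Cd274 at -1.24 ± 0.45. Of 8 Th1-associated genes 0 passed, 7 were negative and 2 were lower adjusted over the list alone, with a median of -0.85. Il12rb2 (above background in 1 and 3) stood at -2.58 ± 0.71, Il18r1 at -1.31 ± 0.43, Il12a at -1.03 ± 0.41 (below background in all 4 Merkel het CLE and 3 CLE libraries) and the cytokine Il18 at -0.74 ± 0.41. In the cell death list Prf1 passed and 13 of 14 members did not, with a median of -0.52 and 1 lower adjusted over the list alone. Prf1 is also a member of the cytotoxic list, and Ctla4 and Cd274 appear in 2 lists each, so the lists are not independent. With quantile normalization the medians were -0.73 (cytotoxic), -0.59 (regulatory T cell), -0.42 (T cell), -0.46 (Th1) and -0.27 (cell death). Background subtraction moved the T cell median to -0.49. Only 2 of the 14 T cell markers were above background in all 12 libraries, with a median of 0.07.

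MHC class I presentation missed the threshold between Merkel het CLE and CLE (fry adjusted p = 0.0502; median -0.91), with 0 of 7 genes past it over all genes and 6 lower adjusted over the list alone. The peptide transporter Tap1 stood at -1.40 ± 0.28, the immunoproteasome subunit Psmb9 at -1.48 ± 0.49, the light chain B2m at -0.91 ± 0.31 and the loading factor Tapbp at -0.89 ± 0.32. B2m turned to 0.73 under quantile normalization. Interferon-gamma-induced genes had a median of -1.23 but did not pass as a list (adjusted p = 0.254), with 0 of 11 past the threshold over all genes and 2 lower adjusted over the list alone. Among them Irf1 stood at -1.54 ± 0.43, Cxcl10 at -2.76 ± 0.87 and Nos2 at -1.75 ± 0.67. The neutrophil list did not pass either (median 0.92, or 1.50 after background subtraction and 0.35 in the 2 members above background in all libraries; adjusted p = 0.598), and 0 of its 7 members passed, over all genes or adjusted over the list alone. Cxcl1 stood at 2.35 ± 0.95, the decoy receptor Il1r2 at -0.94 ± 0.55, S100a9 at 1.85 ± 1.47 and S100a8 at 1.65 ± 1.37; S100a9 and S100a8 turned negative by edgeR, at -0.87 and -0.92. B cell genes missed the threshold (fry adjusted p = 0.0593; median -0.63, or -0.14 with quantile normalization, -0.26 after background subtraction and -0.18 in the 3 members above background in all libraries), and the other 15 lists not named here had adjusted p from 0.254 to 0.844. The cytokine subunit Il27 stood at -1.83 ± 0.43 and NM_019494.1 at -3.27 ± 0.78; both were below background in all 4 Merkel het CLE libraries and in 1 CLE library.

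**Figure D3:**
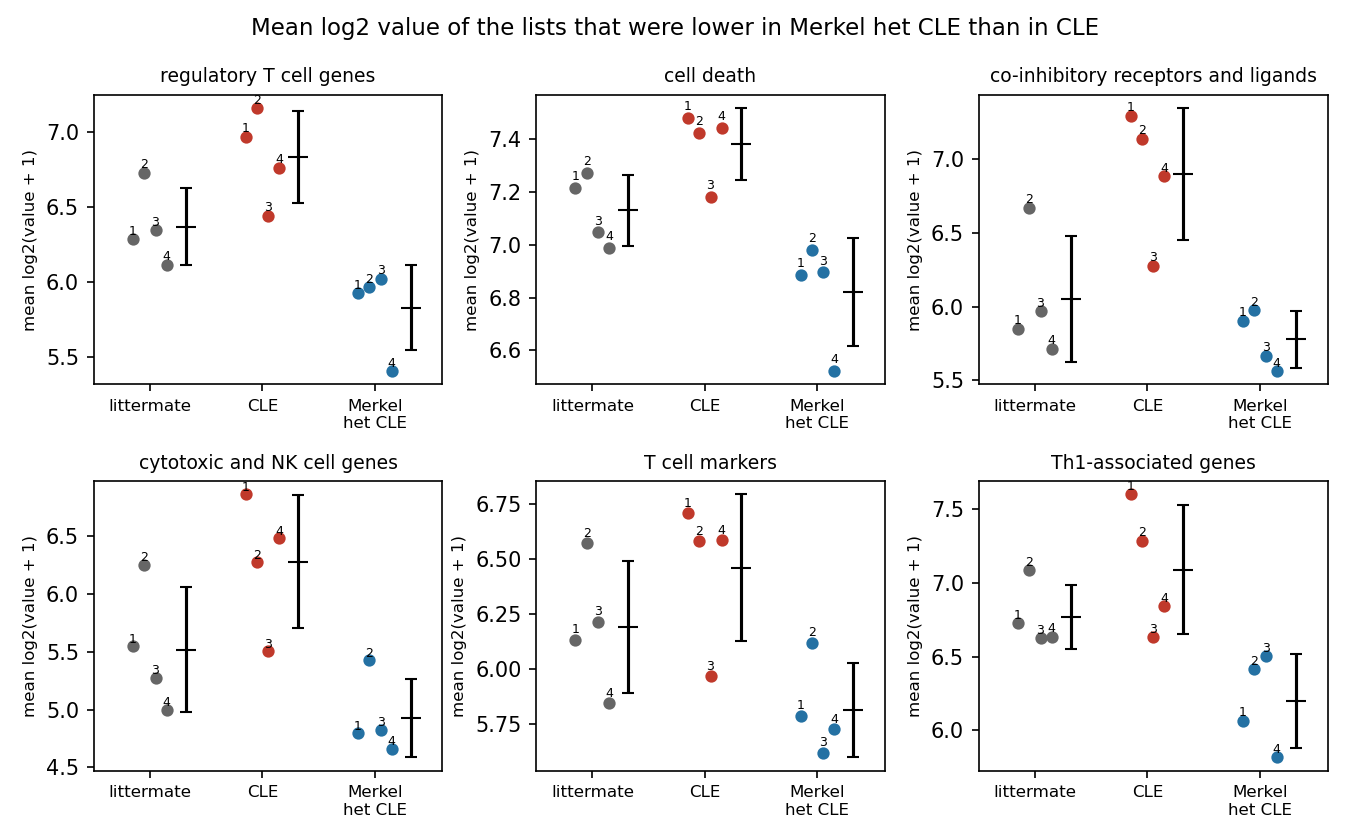
Mean log2(value + 1) over the members of 6 gene lists for each library (digits give the replicate), with the mean and SD of each group. The lists passed as lower in Merkel het CLE than in CLE by fry, but not by camera with an estimated correlation (adjusted p = 0.563 to 0.625). All 4 Merkel het CLE libraries lay below all 4 CLE libraries in 5 of the lists, with T cell markers the exception.

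**Figure D4:**
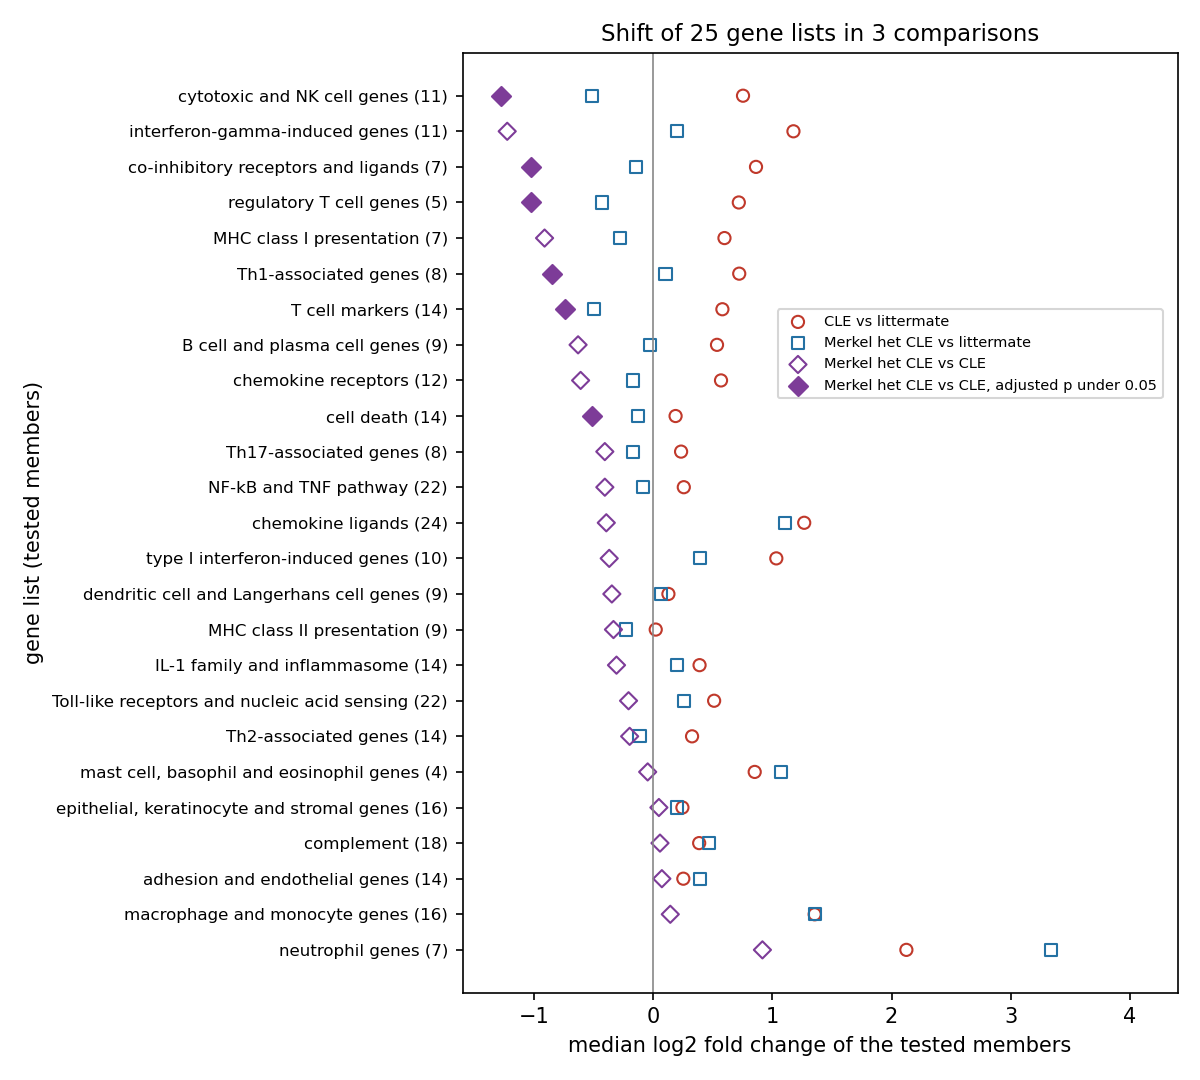
Median log2 fold change of the tested members of 25 gene lists in the 3 comparisons. Filled symbols mark the 6 lists that passed by fry, all of them lower in Merkel het CLE than in CLE (medians -0.52 to -1.27). None of the 6 passed by camera with an estimated correlation (adjusted p = 0.563 to 0.625).

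An exact permutation test of the list means, two-sided, gave p = 0.0286 for the cytotoxic, Th1, regulatory T cell, co-inhibitory and cell death lists and 0.057 for T cell markers. The smallest p that 4 against 4 can give is 0.0286. The same exact p of 0.0286 was reached by the neutrophil list in CLE against littermates, and by the neutrophil, chemokine ligand, Th1, regulatory T cell, mast cell and cell death lists in Merkel het CLE against littermates, none of which passed by fry. The median of all genes lay at -0.26, so relative to it the 6 list medians ran from -0.26 (cell death) to -1.02 (cytotoxic). In simulations of unchanged groups with each lane's own background, the median of all genes was -0.19 and 0 lists passed in 20 draws. On average 4.75 genes were higher and 25.8 lower at an unadjusted p under 0.05, so scaled background alone gave a skew to lower values. It also gave mean list medians of -0.48 (regulatory T cell), -0.40 (cytotoxic), -0.39 (co-inhibitory), -0.33 (Th1), -0.30 (T cell) and -0.20 (cell death). The lowest medians of the same lists in any draw were -0.85, -0.73, -0.65, -0.58, -0.56 and -0.35, where genes were drawn independently, which narrows the spread of a list. By limma 1 of 451 genes passed, 87 had an unadjusted p under 0.05 (12 higher, 75 lower), and edgeR called 11, all lower. The 2 groups did not overlap in 36 genes, or 7.98%, against a chance share of 2.86%. The median 95% interval of a log2 difference reached 0.87 to either side, and in 128 genes it lay within 1 of 0.

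The call of Prf1 was lost under centring, quantile normalization and background subtraction, where 0 genes passed by limma with 65, 68 and 61 at an unadjusted p under 0.05. Over 28 alternatives the log2 difference of Prf1 ran from -2.66 to -1.05 and its adjusted p from 0.0112 to 0.145. Of these, 15 kept it past the threshold. Without CLE 3, 28 genes and 10 lists passed, each lower; without CLE 4 or Merkel het CLE 2, 7 genes passed, without CLE 1 or littermate 2, 2 genes, and without CLE 2 or Merkel het CLE 1, 3 or 4, 0 genes. For the lists, 0 passed without CLE 1, 1 without CLE 2 and 2 without Merkel het CLE 4. Background subtraction left 1 list, the co-inhibitory one, and centring left 3; with the ko/ko libraries alone 0 passed. CLE mice were of the parental strain and Merkel het CLE mice came from a cross, with 0 title numbers in common, so strain and Merkel cell genotype cannot be told apart.

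Log2 differences of CLE and of Merkel het CLE against littermates had the same sign in 320 genes (71.0%), among them S100a9 (5.26 and 7.11), Il1b (3.35 and 4.62) and Il12rb2 (-2.44 and -5.02). Both contrasts share the littermates, and unchanged groups simulated with shared littermates had the same sign in 66.4% of genes on average and 71.2% in the highest of 100 draws, so the share of signs alone does not separate the data from unchanged groups. The differences correlated across genes with r = 0.81, against a simulated 0.50, where genes are not independent replicates. The covariance was 0.912 against a simulated 0.139, a difference of 0.774. With the littermates split into pairs, 1 pair per contrast, r was 0.74, 0.75 and 0.76. The same sign was then seen in 69.0% to 71.4% of genes, with no simulated share for these splits. At an unadjusted p under 0.05, 68 genes appeared in both contrasts, 44 higher in both, 24 lower in both and 0 in opposite directions, where independent lists would share 14.1 and 4.12. As many top genes of the simulated unchanged groups shared 32.7 higher (41 in the highest draw) and 13.2 lower (17 in the highest draw) on average, with genes drawn independently. No gene passed the adjusted threshold in both, since limma called 0 for CLE (25 by edgeR).

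**Figure D5:**
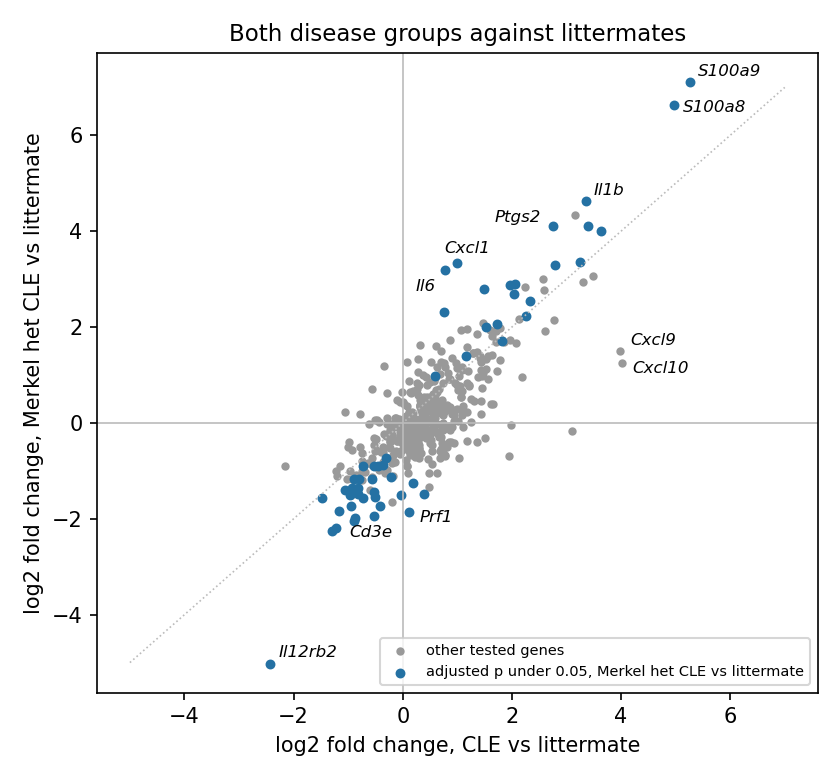
Log2 fold change of each of 451 genes in CLE (horizontal) and in Merkel het CLE (vertical) against littermates, with the 53 genes that passed in the second contrast in blue and a dotted line of equal change. Cxcl10 and Cxcl9 lay far to the right of the line, at 4.02 and 3.98 against 1.26 and 1.50, and Il6 and Cxcl1 above it, at 3.18 and 3.34 against 0.77 and 0.99.

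No gene was called for a trend with the skin disease score within the 8 diseased mice, and the power of this test was not simulated. With group as a term, limma called 0 of 451 genes, with a smallest adjusted p of 0.718 and 20 genes at an unadjusted p under 0.05 (9 higher, 11 lower). The count was 0 in each of the 14 alternatives; edgeR was not run on the score.

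On the Merkel cell list 2 of 12 genes were on the panel and 1, the adhesion molecule Ncam1, was tested. Its mean was 123 units in littermates, 152 in CLE and 196 in Merkel het CLE. The log2 difference was 0.18 ± 0.34, 0.68 ± 0.34 and 0.49 ± 0.34 for CLE against littermates, Merkel het CLE against littermates and Merkel het CLE against CLE (limma adjusted p = 0.736, 0.212 and 0.452). The number of Merkel cells was not measured in these files.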

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

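All tests of explanations below were chosen after the result was seen, except the counts of lists over other splits of the libraries.

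Of the 25 lists, 6 were lower in Merkel het CLE than in CLE: regulatory T cell (adjusted p = 0.0156), cell death (0.0166), cytotoxic and NK cell (0.0178), co-inhibitory (0.0178), T cell (0.0218) and Th1-associated genes (0.0411) by fry of limma. None of them passed by camera with an estimated correlation (adjusted p = 0.563 for the regulatory T cell, cytotoxic and co-inhibitory lists and 0.625 for the other 3). With the preset correlation the cytotoxic, co-inhibitory, T cell and regulatory T cell lists passed by camera, and the Th1-associated and cell death lists did not. Prf1 was the 1 gene that passed between these groups, with a limma adjusted p of 0.0261 and a log2 difference of -1.97. It was above background in 2 CLE libraries and 0 Merkel het CLE libraries. Its call was kept in 15 of 28 alternatives and lost after background subtraction.

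Background scaled up in low-count lanes would make CLE look higher. The 19 list members above background in all 12 libraries still differed by -0.631 ± 0.192 after background subtraction (-0.688 ± 0.168 before), so subtraction did not remove their difference. Their lists were picked for low values in these same libraries, which favours a difference below 0. The 241 other tested genes above background in all 12 libraries differed by -0.182 ± 0.197 before subtraction. The other 35 list members differed by -0.779 ± 0.336 after subtraction, with 18 of them at the floor. This leaves open whether background accounts for those 35. Both ko/ko Merkel het CLE libraries lay below all 4 CLE libraries, which are also ko/ko, in 6 of 6 lists. However, the lists were picked for low values in these same libraries and share members. With ko/ko libraries alone 0 lists passed by fry, so a part played by TLR9 genotype is not excluded. Parental strain against cross could account for all of the difference, since 0 title numbers are shared, so the cause stays open.

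For that comparison the 4 against 4 libraries can be split in 35 ways. As many lists as the real 6 came from 3 splits, with 11 in the highest other split (Merkel het CLE 1, 2 and 4 with CLE 3 against the rest), so chance cannot be excluded. As many genes as the real 1, whichever they were, came from 7 splits. Both this count and that of the lists include the real split. The gene count does not follow Prf1 itself, so it does not decide whether its call is due to chance. The highest other split, Merkel het CLE 1 and 3 with CLE 1 and 4 against the rest, called 59 genes, which points to a structure of the samples; what it is was not tested.

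For Merkel het CLE against littermates, the real split called 53 genes and the highest other split 0. So 1 of 35 splits gave as many, which is the smallest share that 35 splits can give. Calls thus came with the real grouping alone, but a count chosen after the result cannot exclude chance. In the lists the real split and the highest other split gave 0, so all 35 gave as many by construction. For CLE against littermates, the real split called 0 genes by limma (120 at an unadjusted p under 0.05; 25 by edgeR), so all 35 gave as many by construction. The highest other split, with CLE 3 and littermate 2 exchanged, called 5 genes and 11 lists against 0 real lists, and 35 splits gave as many lists, again by construction. At an unadjusted p under 0.05, 3 of 35 splits gave as many genes as the real 120, with 164 in the highest other split, so chance cannot be excluded.

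CLE 3 lay near the littermates: its root-mean-square distance to their mean was 0.570, against 1.95, 1.32 and 1.28 in the other CLE libraries. Littermates 1 to 4 lay 0.392, 0.673, 0.374 and 0.450 from the mean of the 3 others. CLE 3 thus lay farther out than each littermate but littermate 2. Of the 22 genes that rose in Merkel het CLE, CLE 3 was above all littermates in 8, and single littermates were above the 3 others in 1 to 10, so a mislabelled sample is not excluded. Few counts do not account for it, since 2 CLE libraries had fewer than its 299756. A low disease score could play a part, but CLE 2 has the same score of 1 and a distance of 1.32, so the cause stays open.

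Tlr9 was not lower in libraries labelled ko/ko. It was above the background threshold in 7 of 9 of them (2 of the other 3), with a median ratio to the threshold of 1.38, so background may supply part of the signal. The median of the ko/ko libraries was 1.35 units above that of the others, which a probe outside the deleted part could also give. Neither explanation was decided.

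Single libraries far from the other 3 of their group (Dixon's ratio) appeared in 18 of 306 groups, or 5.88%, where chance gives about 1 in 20 (5%). Among CLE libraries, CLE 3 was low in Ccl7 (0.897), Cxcl10 (0.866), Ifi35 (0.903), Pdcd1lg2 (0.863) and the mean of the T cell list (0.830). CLE 4 was low in Cd247 (0.904), and CLE 1 low in Smad3 (0.832) and high in Tlr9 (0.857). Littermate 2 was high in Il2ra (0.877), Il6 (0.860), Nos2 (0.877), the lane factor (0.927) and the scaled negative controls (0.930); Il2ra and Il6 were below background in all 4 littermates. Littermate 1 was high in Psmb9 (0.867) and low in the mast cell list (0.863). Merkel het CLE 1 was low in Gata3 (0.845), Merkel het CLE 2 high in Irf4 (0.903) and Merkel het CLE 4 low in the regulatory T cell list (0.841).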

How the results depend on the processing

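Background subtraction, the filter for genes above background in all 12 libraries, leaving out littermate 2 and CLE 1, and the list tests without single libraries are tests chosen after the results were seen. In the changes of count below, the cause was not tested, except that fits with fewer libraries or genes have less or different information by construction.

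For CLE against littermates, limma called 0 genes in the fit reported and 2 with median centring, 9 with quantile normalization, 108 with array weights and 25 by edgeR. Leaving out single libraries gave 0 to 138, the highest without CLE 3 and 0 in the other 11. The lists went from 0 to 1 with median centring (chemokine ligands), 1 with background subtraction (co-inhibitory) and 0 to 11 without single libraries.

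For Merkel het CLE against littermates, the 53 genes became 85 with median centring, 80 with quantile normalization, 31 without a filter, 34 with a pseudocount of 16, 185 with array weights and 121 with the 2 groups alone. They became 28 with TLR9 genotype as a covariate, 23 among genes above background in all libraries, 102 at an adjusted p of 0.1 and 10 within number 23. The count was 0 by limma with ko/ko libraries alone and without K14Cre+ littermates (77 and 85 at an unadjusted p under 0.05). Leaving out single libraries gave 2 (littermate 3) to 94 (CLE 3). Lists went from 0 to 1 with median centring (regulatory T cell), 1 among genes above background in all libraries (dendritic cell) and 0 to 1 without single libraries. The preset camera called 2, the macrophage and neutrophil lists. Both had adjusted p = 0.867 by camera with an estimated correlation.

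For Merkel het CLE against CLE, the 1 gene became 7 with reference genes rescaled, 8 without a variance trend, 11 by edgeR, 18 at an adjusted p of 0.1 and 3 without littermate 2 and CLE 1. It became 0 by limma with median centring, quantile normalization, no filter, the filter of 50, array weights, the 2 groups alone, ko/ko libraries alone, TLR9 genotype as a covariate, no K14Cre+ littermates, background subtraction, genes above background in all libraries and the score as a covariate. Those 12 fits had 45 to 117 genes at an unadjusted p under 0.05. Leaving out single libraries gave 0 to 28, the highest without CLE 3. The 6 lists became 3 with median centring, 0 by camera with an estimated correlation, 9 by the preset camera (5 lower, 4 higher), 0 with ko/ko libraries alone, 1 with background subtraction and 0 (without CLE 1) to 10 (without CLE 3). Among genes above background in all libraries 0 passed, but 4 of the 6 lists had 2 members left there and were not tested.

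The disease score called 0 genes by limma in all 14 alternatives, with 12 to 49 at an unadjusted p under 0.05. The correlation of the 2 disease contrasts went from 0.81 to 0.74, 0.75 and 0.76 with split littermates, where the shared controls are removed by construction.

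Directions turned in few named genes. Tlr9 in CLE against littermates went from 0.43 to -0.0391 (median centring), -0.17 (quantile normalization) and -0.0563 (without CLE 1), with -0.0563 to 0.90 without single libraries. Tlr9 in Merkel het CLE against littermates went from 0.0036 to -0.12 (reference genes), -0.33 (median centring), -0.22 (quantile), -0.0328 (pseudocount 16), -0.13 (edgeR), -0.48 (ko/ko alone), -0.26 (no K14Cre+ littermates), -0.0227 (random block) and -0.29 to 0.47 without single libraries. Tlr9 in Merkel het CLE against CLE went from -0.43 to 0.0585 with background subtraction and 0.0599 both without CLE 1 and without littermate 2 and CLE 1, with -0.65 to 0.0599 without single libraries. In the same comparison Il2ra turned to 0.0813 (background subtraction), B2m to 0.73 (quantile normalization), and S100a9 and S100a8 to -0.87 and -0.92 (edgeR). The cause was not tested.

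Over all alternatives of the named genes, direction and side of the threshold were kept in 794 of 873 cases for CLE against littermates, 777 of 1168 for Merkel het CLE against littermates and 863 of 933 for Merkel het CLE against CLE. Significance was lost in 0, 367 and 13, gained in 76, 11 and 50, and direction turned in 3, 13 and 7. Since 0 genes passed between CLE and littermates and 1 between Merkel het CLE and CLE, little could be lost there. These counts therefore do not rank the comparisons by stability.

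No paired analysis was possible because replicate numbers only follow the order of the accessions and title numbers do not match mouse to mouse; the 1 number shared by Merkel het CLE and littermates was compared as 2 against 2 without pairs. Depth limits genes near background: the threshold was 116 units in littermate 2 and 106 in CLE 1, against 17.6 to 53.3 in the other 10 libraries.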

Other observations

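The tests of the neutrophil and interferon-gamma lists against each other were chosen after the result was seen; the list counts that come first were not.

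Several lists with few passing members showed single genes that changed in Merkel het CLE relative to littermates, where no list passed by fry. Fcer1a, the IgE receptor chain of mast cells, rose by 2.22 ± 0.65 (SE, n = 4 per group; 2 of 4 littermates above background), the 1 of 4 mast cell, basophil and eosinophil genes to pass (1 adjusted over the list alone; median 1.08). Sting1 rose by 1.70 ± 0.50, 1 of 22 Toll-like receptor and nucleic acid sensing genes (0 adjusted over the list alone; median 0.26). Of 14 adhesion genes 1 passed as higher and 13 did not pass (0 adjusted over the list alone; median 0.39). The complement regulator Cd55 fell by 1.36 ± 0.38, 1 of 18 complement genes (0 adjusted over the list alone; median 0.47). Tgfb2 fell by 1.57 ± 0.38, 1 of 16 epithelial and stromal genes (1 adjusted over the list alone; median 0.20).

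Gata3 was the 1 of 14 Th2-associated genes to pass in that comparison, and it fell (1 higher and 2 lower adjusted over the list alone; median -0.12). Of 8 genes in the Th17 list 1 rose (Il6), 1 fell and 6 did not pass (2 higher and 3 lower adjusted over the list alone; median -0.17). Irf4 fell as 1 of 9 dendritic cell genes (1 adjusted over the list alone), with a median of 0.06 and a mean of -0.31. Ikzf2 fell as 1 of 5 regulatory T cell genes (1 adjusted over the list alone; median -0.43), and Prf1 as 1 of 14 cell death genes (1 adjusted over the list alone; median -0.13). Among 14 IL-1 family genes Il1b rose and Il18r1 fell (the same adjusted over the list alone; median 0.20). Among 12 chemokine receptors Cxcr2 rose and Ackr4 fell (3 higher and 2 lower adjusted over the list alone; median -0.17).

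Some of these small medians turned with the scaling. With median centring the Toll-like receptor, epithelial, dendritic cell and IL-1 medians were -0.08, -0.14, -0.27 and -0.14; with background subtraction the Th17, chemokine receptor and cell death medians were 0.03, 0.06 and 0.02.

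No member passed, over all genes or adjusted over the list alone, in type I interferon-induced (0 of 10; median 0.39), B cell (0 of 9; median -0.03), MHC class I (0 of 7; median -0.28), MHC class II (0 of 9; median -0.23) and co-inhibitory genes (0 of 7; median -0.14) in Merkel het CLE against littermates. For CLE against littermates, lists not described above with members past the threshold when adjusted over the list alone were Th1 (3 higher, 1 lower), adhesion (2 higher), epithelial (1 higher, 1 lower), mast cell, complement and co-inhibitory genes (1 higher each). For Merkel het CLE against CLE they were dendritic cell genes (2 lower) and chemokine ligands (1 lower).

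A hypothesis from these values is that fewer Merkel cells go with more neutrophil and less interferon-gamma signal. Per library, the neutrophil mean minus the interferon-gamma mean was 2.16 ± 1.12 in Merkel het CLE, 0.168 ± 2.23 in CLE and -1.01 ± 0.405 in littermates (SD, n = 4). The difference of 1.99 between the disease groups had an exact permutation p of 0.143. CLE 1 (2.88) lay among the Merkel het CLE libraries and CLE 4 (-2.59) below all littermates, so the hypothesis is not supported at this number of mice.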
